A study of Mus musculus with 3 samples.

How the data were processed

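Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was measured in 3 libraries of mouse pro-B cells, 1 library per antibody. The antibodies were raised against symmetric dimethylation of arginine 2 of histone H3 (H3R2me2s), against the same mark together with trimethylation of lysine 4 (H3R2me2sK4me3, called the combined mark), and against H3K4me3 alone. Per the labels, the first 2 antibodies were made in the submitting laboratory and the third was a commercial one. No input or IgG library was among the samples used here.

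Per the labels' protocols, nuclei were sonicated, the libraries were amplified with 15 PCR cycles, fragments of 100 to 500 bp were taken from a gel, and sequencing was on the Genome Analyzer. Per the submitters' processing notes, the genome build was mm9. The aligner, the rules on mismatches and repeated sequence, and any removal of repeated reads were not given in the sources used here. The deposited files hold 1 mapped read of 39 bases per line, so that read counts per stretch of genome are raw counts with no scaling by the authors.

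From these files each read was moved 75 bp in its 3-prime direction and counted in 1 kb bins. There were 2285014 bins with a read in any library, and the genome-wide mean was taken over them. A bin was called enriched at 4 times the mean or more, and at no fewer reads than the smallest count with a Poisson upper tail under 1e-06. The limits came to 15 reads for H3R2me2s, 16 for the combined mark and 25 for H3K4me3. Poisson counting alone would pass 1.73, 0.475 and 0.0175 bins at those limits. Enriched bins no more than 1 kb apart were merged into regions. Background was the mean of bins more than 5 kb from any enriched bin, and levels are given as multiples of it. A net level is the level less background. Reads scaled to the total mapped reads of the library are written CPM.

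Shared bins were set beside the number that independent placement gives (the product of both counts over the number of bins). Shares have exact 95% Clopper-Pearson intervals, and ratios of reads have exact 95% binomial intervals. These cover counting error only, since PCR reads without molecular identifiers are not independent molecules. With 1 library per antibody no p-value between antibodies was computed, and no difference has a replicate check. Correlations across bins used all reads, and also random parts of 3461882 reads per library, which put the libraries at equal depth and give the correlation of a library with itself. For classes of H3K4me3 level, bins were called and ranked on a random part of the H3K4me3 reads and measured on the rest, with intervals from 200 bootstrap draws over bins. Log2 values used a pseudocount of 0.5 CPM.

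Profiles were drawn in 100 bp bins to 5 kb around the highest bin of each region, with 200 bootstrap draws over regions. A trial with smoothed summits had shown a dip at the centre, and the single highest bin was chosen after that was seen. Because the first profile plot had a sharp centre, H3K4me3 summits were then also chosen on a random part of the reads and measured on the remaining reads, and the centre was also placed at random bins, under each of the 3 read shifts. Nucleosome spacing was read from distances between distinct read starts on the same strand in H3K4me3-enriched bins, after removal of a cubic trend. Regions per megabase and protein-coding genes per megabase were compared over 20 chromosomes by a two-sided permutation test with 100000 draws and Benjamini-Hochberg adjustment over 3 libraries. Gene numbers per chromosome came from a table for GRCm38, of which no coordinates were used.

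Evenness of the chromosome 2 block was measured as the CV of read density over 100 bp bins, from the number of distinct read starts per bin, corrected for positions hit more than once and for sampling. Its interval came from 200 bootstrap draws over bins, and the estimate was tested on simulated bins of known CV. It was compared with the 200 regions with most reads of each of 2 width ranges.

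The rules for calling bins, overlaps, correlations and named regions were written before the data were examined. The background definition, the level and width classes, the division of reads into parts, spacing, gene density, chromosome X and the chromosome 2 block were chosen after looking at the data. Regions were named by rule. For each comparison these were the 5 with the highest and the 5 with the lowest CPM ratio, among regions enriched in either library with at least 30 reads in both together. They were ranked by the interval bound nearest to 1. The 5 regions with most reads in each library were also named. A ratio against 0 reads was bounded with 3 reads per library. The calling rule was tested on simulated data of 300000 bins per library, with 200 planted bins per level. Its limits were set there from the mean of the simulated bins, which lay near background. Background was 2.35 reads per bin for H3R2me2s, 1.86 for the combined mark and 2.98 for H3K4me3, where the real means were 3.03, 3.12 and 6.08. At 8 times background it called 88.5% of planted bins for H3R2me2s, 83.0% for the combined mark and 97.5% for H3K4me3. At 4 times background it called 11.0%, 8.00% and 22.0%. With the uneven background of that simulation, its false calls scaled to all bins were 122, 68.7 and 344, above the Poisson numbers. The limits in the simulation were lower than those used on the data, most of all for H3K4me3. The shares called and the false calls are therefore higher than the limits used on the data would give.

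Planned results that need an mm9 gene annotation or genome sequence were not run. They were read shares and levels at transcription start sites, gene lists and promoter classes by CpG content. The regions therefore carry positions and no gene names, and profiles were centred on region summits. Results were recomputed under 9 other settings written before the data were examined and 3 added after seeing the data. They covered repeated reads, the read shift, the calling limits, equal depth, local background, bin width, chromosome X and Y, the chromosome 2 segment and the pseudocount. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.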

Results

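Maps of 3 histone modification states were compared in Abelson-transformed pro-B cells that the labels describe as lacking RAG2. Pro-B cells are early B-lineage cells, Abelson virus keeps them growing in culture, and RAG2 is a subunit of the recombinase that assembles antigen receptor genes. There were 6923765 reads for H3R2me2s, 7128852 for the combined mark H3R2me2sK4me3 and 13898471 for H3K4me3. Reads that repeated a position and strand made up 5.22%, 2.64% and 6.20% of them. The genotype was not checked in the reads. A block on chromosome 2, described below, held 3352 reads of H3R2me2s and 3208 of the combined mark but 54 of H3K4me3. A nearby stretch of 1800 bp held 197, 390 and 17 reads in the same order. In a 1 Mb window on chromosome 4, background was 0.508, 0.499 and 0.966 of the genome-wide level. The preparations may therefore differ in more than the antibody, which bears on every comparison with H3K4me3. No antibody had a second library, so intervals describe counting error within each library.

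H3R2me2s formed 13846 regions, the combined mark 13180 and H3K4me3 18461. The regions were short, with median widths of 2, 2 and 3 kb. The share of reads in enriched bins was 14.8% for H3R2me2s (14.79 to 14.85), 33.7% for the combined mark (33.66 to 33.73) and 45.1% for H3K4me3 (45.07 to 45.12). With every library thinned to the depth of the shallowest, the shares were 14.8%, 33.9% and 44.0%. Enriched bins numbered 28193, 33137 and 56039. They fell to 15379, 25100 and 34055 at 8 times the mean and to 12221, 17939 and 23249 against local background.

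The comparison of H3R2me2s with H3K4me3 asks whether the arginine mark lies where the lysine mark lies. Most bins called for H3R2me2s were also called for H3K4me3, while much H3K4me3 chromatin was not called for H3R2me2s. Of the H3R2me2s bins, 93.0% were also enriched for H3K4me3 (92.7 to 93.3), which was 26209 bins where independent placement gives 691. Of the H3R2me2s regions, 88.3% held an H3K4me3 bin (87.7 to 88.8). These shares cover called bins, which hold 14.8% of the H3R2me2s reads. The share of bins ranged from 89.97% on chromosome 1 to 98.9% on chromosome X. In the other direction, 46.8% of H3K4me3 bins were enriched for H3R2me2s (46.4 to 47.2). Across H3K4me3 bins, levels of both marks rose together, with a Spearman rho of 0.839. Bins are not independent replicates. At equal depth r was 0.818 between the marks and 0.819 between separate parts of the H3R2me2s reads, beside 0.915 between parts of the H3K4me3 reads. The highest r that these allow is 0.866, of which the marks reached 0.945.

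The H3K4me3 bins not called for H3R2me2s were the weaker ones. In 5 classes of rising H3K4me3 level, the share of bins enriched for H3R2me2s was 7.12%, 15.9%, 46.2%, 89.6% and 99.9%. Net H3R2me2s per net H3K4me3 fell from 0.270 (0.267 to 0.274) in the weakest class to 0.210 (0.208 to 0.212) in the middle one, then rose to 0.213 and 0.242 (0.241 to 0.243). A local background above the genome-wide one was not subtracted and would raise this ratio most in the weak classes, so the fall may depend on the background used. The mean H3R2me2s level in the weakest class was 3.59 times a background of 2.35 reads per bin, which is below the calling limit of 15 reads. Broad H3K4me3 regions nearly always held a bin called for H3R2me2s, and they have more bins in which a call can fall. It was called in 15.2% of 5213 regions of 1 kb (14.2 to 16.2), in 69.3% of 6939 regions of 2 to 3 kb, and in 408 of 409 regions of 10 kb or more. With the libraries thinned to equal depth, it was called in 20.2% of 5005 regions of 1 kb and 77.2% of 6973 regions of 2 to 3 kb. Over 5 classes of rising width the mean H3R2me2s level went from 4.22 to 11.2 times background, while net H3R2me2s per net H3K4me3 was 0.242, 0.227, 0.232, 0.236 and 0.235.

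**Figure D1:**
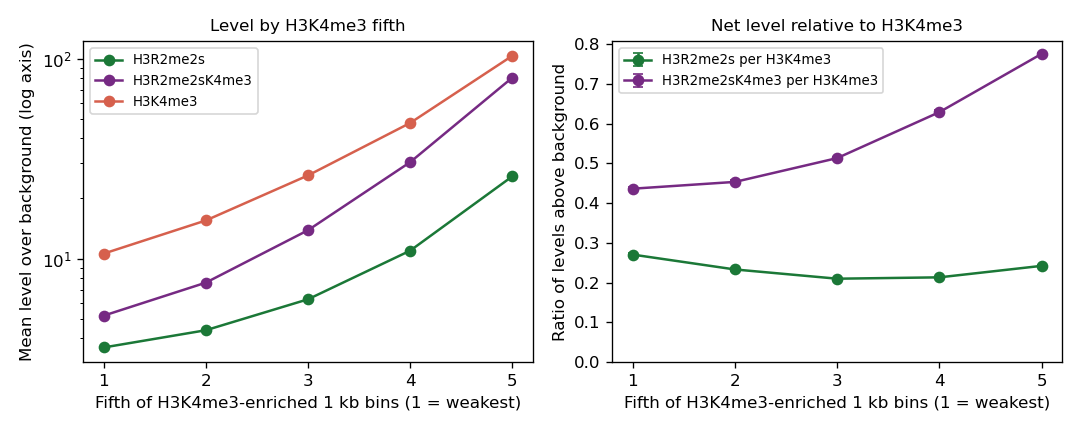
Mean level over background (left, log axis) and net level relative to H3K4me3 (right) in 5 classes of H3K4me3-enriched 1 kb bins, with class 1 the weakest; bars are 95% bootstrap intervals over bins. Net of the genome-wide background, the combined mark per H3K4me3 rises from 0.436 to 0.775, while H3R2me2s per H3K4me3 falls from 0.270 to 0.210 in class 3 and rises to 0.242 in class 5.

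The median CPM ratio of H3R2me2s to H3K4me3 over regions was 0.412. Scaling to background in place of all reads moved log2 ratios by -0.67. Over 10623 regions with 30 reads or more in both libraries, the SD of the log2 ratio was 0.34, where counting alone gives 0.19. That limit on reads leaves out regions with little H3R2me2s, among them the 5 with the lowest ratios. The highest ratio was at chromosome 2, 101481001 to 101491000 (mm9), at 15.8 (14.3 to 17.5), with 3403 H3R2me2s reads and 432 H3K4me3 reads. A flat block of 3126 bp within it held 3352 and 54 of these reads. Ranked by the bound nearest to 1, it was followed by chromosome 1, 24618001 to 24622000, at 6.68 (5.25 to 8.56). Next came chromosome 8, 108760001 to 108762000, at 10.6 (4.67 to 28.2), and chromosome 2, 22444001 to 22446000, at 6.74 (4.38 to 10.7). The last was chromosome 5, 96564001 to 96566000, at 8.25 (3.91 to 19.4). The lowest ratios were all in narrow regions. At chromosome 10, 121273001 to 121274000, there were 0 H3R2me2s reads and 63 H3K4me3 reads, so that H3R2me2s was at least 10.5-fold lower with 3 reads set in place of 0. The exact interval of that ratio, which also covers the H3K4me3 count, reached 0.121. On the same terms it was at least 6.64-fold lower (interval to 0.194) at chromosome 12, 77278001 to 77279000, and at least 6.14-fold lower (interval to 0.210) at chromosome 10, 120788001 to 120789000. The ratio was 0.0521 (0.0062 to 0.195) at chromosome 12, 74154001 to 74156000, and 0.0352 (0.00088 to 0.204) at chromosome 11, 82853001 to 82854000.

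The comparison of the combined mark with H3K4me3 asks whether the combined mark lies where the lysine mark lies, and how their signals relate. Levels from different antibodies were not calibrated against each other here, so ratios between them are not shares of marked tails. The combined mark was called almost only within H3K4me3 chromatin and its signal relative to that of H3K4me3 was higher where H3K4me3 was strong. Of its bins, 99.1% were enriched for H3K4me3 (99.02 to 99.23), which was 32848 bins where independent placement gives 813. Of H3K4me3 bins, 58.6% were enriched for the combined mark (58.2 to 59.0). The Spearman rho across H3K4me3 bins was 0.920. At equal depth r was 0.899, beside 0.920 within the combined mark and 0.915 within H3K4me3.

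Net of the genome-wide background, the combined mark rose faster than H3K4me3 from class to class, where H3R2me2s did so only over the stronger classes. The net combined mark per net H3K4me3 was 0.436 (0.432 to 0.442), 0.453, 0.513, 0.629 and 0.775 (0.773 to 0.779) from the weakest to the strongest class. The median CPM ratio over regions was 0.714, and scaling to background moved log2 ratios by -0.28. The highest ratio was again at the chromosome 2 region, at 15.0 (13.6 to 16.6). The chromosome 8 region had 8.08 (3.46 to 21.8), the chromosome 1 region 3.35 (2.56 to 4.40) and the chromosome 2 region at 22444001 to 22446000 had 3.20 (1.96 to 5.32). Chromosome 17, 80865001 to 80866000, had 3.90 (1.74 to 9.33). Among the lowest, the combined mark was at least 6.16-fold lower (interval to 0.210) at chromosome 14, 93629001 to 93630000, and at least 5.98-fold lower (interval to 0.217) at chromosome 1, 179394001 to 179395000, with 3 reads in place of 0. The ratio was 0.172 (0.0918 to 0.297) at chromosome 11, 117209001 to 117212000. It was 0.139 (0.0546 to 0.298) at chromosome 12, 120085001 to 120087000, and 0.113 (0.0299 to 0.303) at chromosome 5, 53603001 to 53606000.

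The third comparison sets H3R2me2s beside the combined mark. Most bins called for H3R2me2s were also called for the combined mark. Net of the genome-wide background, the combined mark was relatively stronger where H3K4me3 was strong. Of H3R2me2s bins, 85.3% were enriched for the combined mark (84.9 to 85.7), and 72.6% of combined-mark bins were enriched for H3R2me2s (72.1 to 73.1). The net combined mark per net H3R2me2s rose from 1.61 in the weakest H3K4me3 class to 3.20 in the strongest. A local background above the genome-wide one would lower this ratio most in the weak classes. It was not measured, so the rise may depend on the background used. The median CPM ratio of H3R2me2s to the combined mark was 0.4996, and scaling to background moved log2 ratios by -0.38. The lowest ratios were at chromosome 5, 135113001 to 135116000, at 0.233 (0.171 to 0.313), and at chromosome X, 103222001 to 103224000, at 0.243 (0.170 to 0.341). They were followed by 0.262 (0.198 to 0.343) at chromosome 13, 97157001 to 97160000, 0.285 (0.226 to 0.355) at chromosome 13, 22085001 to 22089000, and 0.272 (0.205 to 0.357) at chromosome 9, 96377001 to 96380000. All 5 of these regions held over 300 H3K4me3 reads. The highest ratios rested on few reads. They were 8.49 (3.02 to 33.0) at chromosome 7, 121240001 to 121242000, 7.21 (2.81 to 23.6) at chromosome 1, 154432001 to 154434000, and 6.95 (2.42 to 27.3) at chromosome 9, 115986001 to 115988000. The ratio was 4.80 (2.31 to 11.2) at chromosome 5, 113548001 to 113551000, and 5.15 (2.11 to 15.1) at chromosome 11, 44487001 to 44489000.

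Together the 3 libraries marked 58280 bins. All 3 marks were called in 24023 of them, or 41.2%. H3K4me3 alone was called in 21005, H3K4me3 with the combined mark in 8825, and H3R2me2s with H3K4me3 in 2186. H3R2me2s alone was called in 1952 bins, the combined mark alone in 257, and both without H3K4me3 in 32. These classes depend on the calling limits. Bins called for H3K4me3 alone had means of 3.42 times background for H3R2me2s and 4.94 times for the combined mark. Median H3K4me3 was 4.03 times background in bins called for H3R2me2s alone and 6.71 times in those called for the combined mark alone. A mark that was not called was therefore not shown to be absent. Whether any antibody binds the other marks was not analysed here, and no input library was used to remove local bias.

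The regions with most reads were largely shared. Chromosome 14, 79914001 to 79925000, had 135 CPM of H3R2me2s, 333 of the combined mark and 350 of H3K4me3. Chromosome 12, 114658001 to 114670000, had 182, 424 and 318 CPM. A 54 kb region at chromosome 11, 3051001 to 3105000, had nearly equal values of 316, 293 and 321 CPM. It stood at 17.2, 20.8 and 27.8 times background, so its rank by reads rests in part on its width. A local bias common to the libraries was not removed there, as no input library was used. Chromosome 11, 11586001 to 11597000, had 117, 287 and 301 CPM. Chromosome 3, 60272001 to 60291000, was among the strongest for H3R2me2s with 117 CPM, and chromosome 6, 134866001 to 134885000, was among the strongest for H3K4me3 with 304 CPM. The chromosome 2 region ranked highest in H3R2me2s (491 CPM) and the combined mark (467 CPM), and had 31.1 CPM of H3K4me3.

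**Figure D2:**
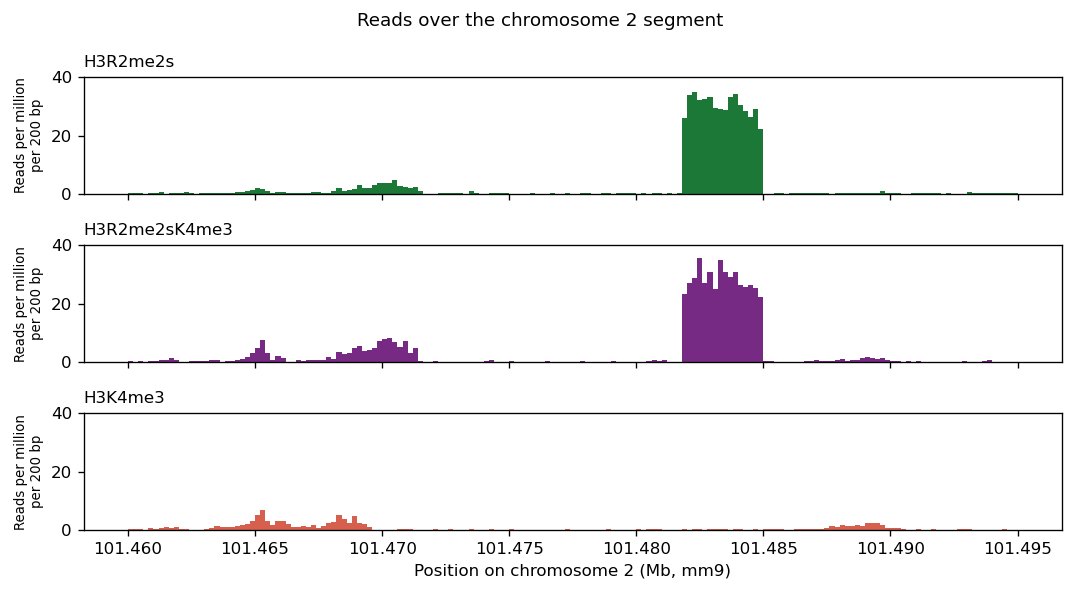
CPM per 200 bp (vertical axis) along a segment of chromosome 2 (mm9, Mb) in the 3 libraries. A block of 3126 bp with sharp edges holds 484 CPM of H3R2me2s, 450 CPM of the combined mark and 3.89 CPM of H3K4me3.

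Around H3K4me3 summits the mean profiles of all 3 marks were highest at the centre, and H3K4me3 reached farther out. Profiles were averaged over regions and both directions, and distances between summits of different marks within a region were not measured. Between 1 and 2 kb from the summit lay 20.4% of net H3K4me3 (20.1 to 20.6), 18.0% of net H3R2me2s (17.7 to 18.4) and 17.5% of the net combined mark (17.2 to 17.9). Centred on H3R2me2s summits the shares were 21.6%, 15.7% and 17.2%. Centred on combined-mark summits they were 21.0%, 17.3% and 16.6%. With summits chosen on separate H3K4me3 reads, the shares were 20.8%, 18.3% and 17.7%.

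At the centre, the highest 100 bp bin stood above its neighbours in every library, by an amount that depended on the read shift. With summits chosen on separate reads, the central 100 bp bin held 1.81 times the H3K4me3 reads of the bins beside it, 1.95 times for H3R2me2s and 1.89 times for the combined mark. At random bins of the same regions the values were 1.01, 1.02 and 1.01. With reads not moved the central values were 1.29, 1.35 and 1.36, and with reads moved 150 bp they were 1.43, 1.52 and 1.51. The peak width is not given as a property of the marks, because it followed the read shift and the choice of summit. The full width at the 50% level of H3K4me3 was 186 bp with summits and levels from the same reads and 329 bp with summits from separate reads. With summits and levels from the same reads it was 421 bp with reads not moved and 476 bp with reads moved 150 bp, and for H3R2me2s it went from 184 bp to 480 and 509 bp. With summits from separate reads, peak over flank for H3K4me3 fell from 30.1 to 26.9. Those summits rested on fewer reads, and how much that adds to the changes in width and height was not measured.

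**Figure D3:**
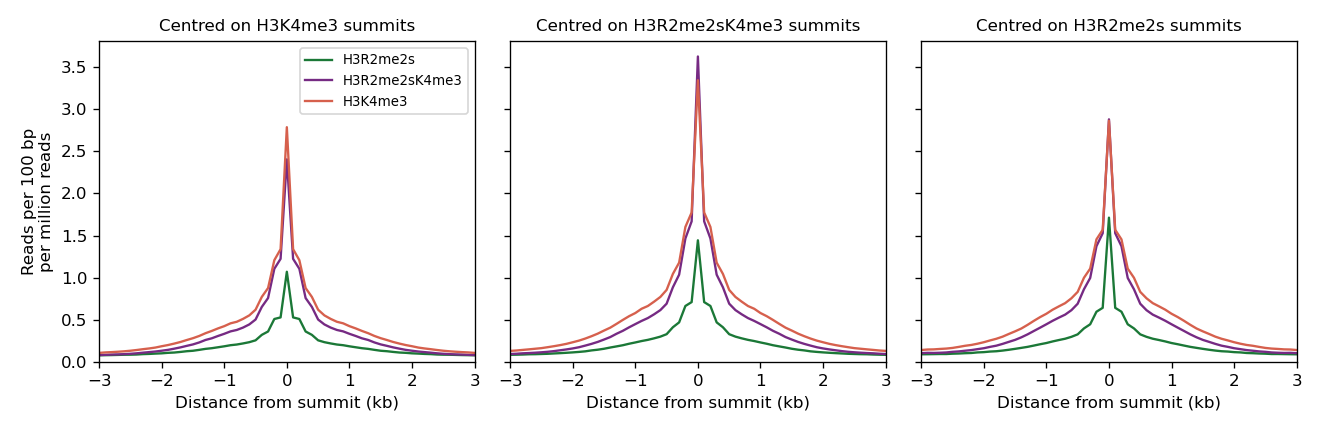
Mean CPM per 100 bp against distance (kb) from region summits chosen in each library, averaged over both directions. The mean profiles of all 3 libraries are highest at the centre, and H3K4me3 at its own summits stands at 30.1 times the flank, against 26.9 times with summits chosen on separate reads (not drawn).

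Read starts within H3K4me3 chromatin recurred at nucleosome-like distances in the 3 libraries. The spacing was 186 bp for H3R2me2s, 184 bp for the combined mark and 182 bp for H3K4me3. The nearest peak stood above its trough by 0.17, 0.12 and 0.08 on the log2 scale. Peaks lay at 190, 367, 568 and 742 bp for H3R2me2s, at uneven steps. They lay at 192, 375, 575 and 738 bp for the combined mark and at 189, 372, 566 and 731 bp for H3K4me3. For H3R2me2s the curve was higher over the trend at 740 bp (0.033) than at 565 bp (0.019). No error was estimated for these values, so the 3 spacings are not read as different.

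**Figure D4:**
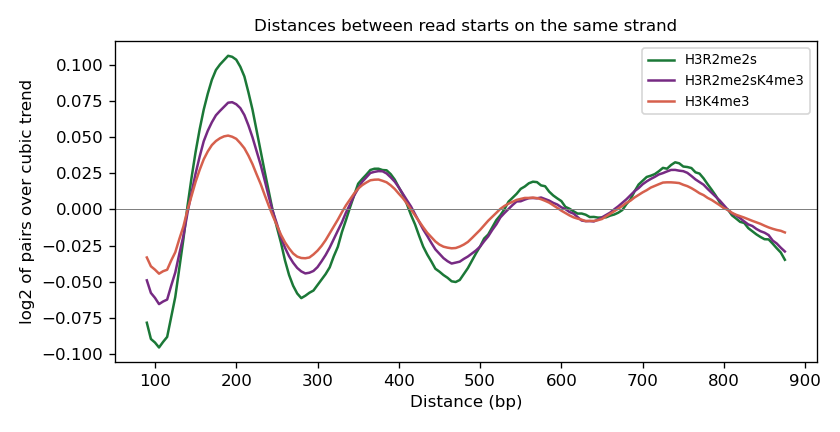
Log2 of the number of same-strand pairs of read starts over a cubic trend, against their distance in bp, in H3K4me3-enriched bins; each line is 1 library. The peaks nearest to 0 lie at 190 bp for H3R2me2s, 192 bp for the combined mark and 189 bp for H3K4me3.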

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

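The settings that left out chromosomes X and Y or the chromosome 2 segment, the other pseudocount, and the check of summits on separate reads, were chosen after seeing the data. Of 215 values recomputed under 12 settings, 105 moved by less than their interval, the SD over chromosomes or 1.5 times for counts, and 110 moved more. Of the 105, 10 could not move: 7 at 2 times the mean, where the limits stayed at 15 reads for H3R2me2s and 16 for the combined mark and only the H3K4me3 limit fell, from 25 to 22, and 3 at equal depth, where the H3R2me2s library was not thinned. Intervals here are narrow, so small moves count. In every setting that called bins, at least 91.7% of H3R2me2s bins and at least 94.2% of combined-mark bins were enriched for H3K4me3. Leaving out the chromosome 2 segment moved no count, correlation or overlap. No paired analysis was possible because each antibody had 1 library, and no library could be left out. Settings for transcription start sites, gene lists and CpG classes were not run, because they need an mm9 annotation or genome. The calling rule leaves out weak sites. Background was 0.777 of the mean for H3R2me2s, 0.597 for the combined mark and 0.490 for H3K4me3, so 4 times background lay below 4 times the mean. In the simulation, with its lower limits, 11% of H3R2me2s bins planted at 4 times background were called. At equal depth, enriched H3K4me3 bins fell from 56039 to 49714, and the share of them enriched for H3R2me2s rose from 46.8% to 52.0%. How much depth adds to the shares called in the simulation was not tested. Except where stated, the cause of a move was not tested.

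The share of H3R2me2s bins enriched for H3K4me3 (93.0%) was 96.1% with 1 read per position, 93.3% with reads not moved, 93.4% with reads moved 150 bp, 93.7% at 2 times the mean, 99.6% at 8 times, 91.7% at equal depth, 98.9% at a stricter Poisson tail, 95.5% with local background, 97.4% in 500 bp bins and 95.5% on autosomes. On autosomes the H3R2me2s calling limit rose from 15 to 16 reads. The share of H3R2me2s bins enriched for the combined mark (85.3%) was in the same order 90.3%, 85.9% and 86.0%, then 99.1% at 8 times the mean, 85.9% at equal depth, 95.7% at the stricter tail, 95.9% with local background, 93.2% in 500 bp bins and 89.5% on autosomes. The share of combined-mark bins enriched for H3K4me3 (99.1%) was 98.9% with 1 read per position, 99.4% at 2 times the mean, 98.9% at 8 times, 97.6% at equal depth, 99.8% at the stricter tail and 94.2% with local background. The share of H3K4me3 bins enriched for H3R2me2s (46.8%) was 42.2% with 1 read per position, 42.3% at 2 times the mean, 45.0% at 8 times, 52.0% at equal depth, 38.5% at the stricter tail, 50.2% with local background, 34.7% in 500 bp bins and 43.6% on autosomes.

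The Spearman correlation across H3K4me3 bins between H3R2me2s and H3K4me3 (0.839) was 0.821 at 2 times the mean, 0.881 at 8 times, 0.852 at equal depth, 0.932 with local background and 0.798 in 500 bp bins. Between the combined mark and H3K4me3 (0.920) it was 0.914 with 1 read per position, 0.911 at 2 times the mean, 0.935 at 8 times, 0.967 with local background and 0.895 in 500 bp bins. Between H3R2me2s and the combined mark (0.833) it was 0.814 at 2 times the mean, 0.900 at 8 times, 0.858 at equal depth, 0.946 with local background and 0.800 in 500 bp bins. With a pseudocount of 0.1 CPM, r at equal depth fell from 0.818 to 0.775 between H3R2me2s and H3K4me3, from 0.899 to 0.873 between the combined mark and H3K4me3, and from 0.832 to 0.773 between H3R2me2s and the combined mark. At 8 times the mean there were 15379 enriched bins and 8567 regions of H3R2me2s and 34055 bins of H3K4me3. With local background there were 12221 bins and 9048 regions of H3R2me2s, 17939 bins of the combined mark and 23249 bins of H3K4me3. In 500 bp bins there were 89005 H3K4me3 bins, as bins of a smaller width are more numerous.

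Profile widths moved with the read shift. Peak over flank at H3K4me3 summits with 1 read per position was 12.9 for H3R2me2s, 28.9 for the combined mark and 24.9 for H3K4me3. It was 11.4, 26.4 and 26.5 with reads not moved, and 11.4, 26.0 and 26.0 with reads moved 150 bp. At equal depth it was 31.7 for H3K4me3. The full width at the 50% level, in the same order of libraries, was 192, 251 and 209 bp with 1 read per position, 480, 468 and 421 bp with reads not moved, 509, 510 and 476 bp with reads moved 150 bp, and 190, 242 and 179 bp at equal depth. The share of net signal at 1 to 2 kb was 21.3% for H3K4me3 with 1 read per position. With reads not moved it was 18.6% for H3R2me2s and 17.9% for the combined mark, and with reads moved 150 bp it was 18.6% for H3R2me2s.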

Other observations

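All tests of explanations in this part were chosen after the result was seen, except the test of ranking on noisy counts, and all other analyses in this part were also chosen after looking at the data.

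Chromosomes with more genes per megabase tended to have more regions of every mark per megabase, with chromosome X as an exception. Over 20 chromosomes, regions per megabase followed protein-coding genes per megabase with r of 0.81 for H3R2me2s (permutation p = 3e-05, adjusted 6e-05), 0.82 for the combined mark (p = 4e-05, adjusted 6e-05) and 0.76 for H3K4me3 (p = 0.00015, adjusted 0.00015). Spearman rho was 0.83 (permutation p = 4e-05), 0.83 (p = 2e-05) and 0.78 (p = 4e-05), each with an adjusted p of 4e-05. Without chromosomes 7 and 11, r was 0.79, 0.84 and 0.77. Chromosome X, with 8.53 genes per megabase, had the fewest regions per megabase, at 2.67 for H3R2me2s, 3.30 for the combined mark and 4.37 for H3K4me3, and on autosomes alone r was 0.87, 0.86 and 0.82. Calling limits were genome-wide and background on chromosome X was lower, so its sites reached them less easily, which was not corrected for. Chromosomes of a library are not replicates.

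Chromosome X differed in the balance of the marks. Background there was 0.524, 0.544 and 0.548 of the genome-wide background for H3R2me2s, the combined mark and H3K4me3. Calling limits were genome-wide, so a bin on chromosome X had to stand higher over its own background to be called. Whether that selection gives the differences below was not tested. For this comparison, net levels are less each chromosome's own background, unlike those of the classes above. In its H3K4me3 bins, net H3R2me2s per net H3K4me3 was 0.217, below the 0.221 to 0.237 of the 19 autosomes. The net combined mark per net H3K4me3 was 0.699, above their 0.635 to 0.670. The mean level of the combined mark in those bins, at 24.1 times the genome-wide background, lay within the autosomal 23.3 to 26.4, while H3K4me3 at 34.3 lay below 35.7 to 39.3 and H3R2me2s at 7.85 lay below 8.99 to 9.98. Among 2472 background windows of 1 Mb, the lowest ratio of H3R2me2s to H3K4me3 was at chromosome 4, 152000001 to 153000000. Background there was 0.508 of the genome-wide level for H3R2me2s, 0.499 for the combined mark and 0.966 for H3K4me3, and it was also the window with the lowest ratio of the combined mark to H3K4me3. As these are background levels, the difference may lie in the preparations and not in the marks, which was not tested. Over all windows, background correlated at r of 0.98 between H3R2me2s and the combined mark, 0.92 between H3R2me2s and H3K4me3, and 0.94 between the combined mark and H3K4me3. Windows are not replicates.

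Beside the block described next, a stretch of 1800 bp at chromosome 2, 101469601 to 101471400, held 197 reads of H3R2me2s (46.5 times background), 390 of the combined mark (116 times) and 17 of H3K4me3 (3.17 times). Just before it, at 101468001 to 101469400, there were 79, 175 and 327 reads (24.0, 67.2 and 78.4 times background). Over the 10000 bp after it, at 101471601 to 101481600, levels were 1.91, 2.47 and 2.22 times background. H3K4me3 thus dropped before the 1800 bp stretch and the other libraries only after it. Whether the marks or the DNA of the preparations differed there was not tested. The 9 windows of 200 bp in the 1800 bp stretch held 15 to 32 reads of H3R2me2s and 23 to 58 of the combined mark. They held 0 to 5 reads of H3K4me3, and 2 of them had 0. In a GRCm38 gene table Rag1 and Rag2 are neighbours on chromosome 2, and whether either stretch or the block lies in one of them was not analysed here, as no mm9 annotation was used.

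The strongest signal of the H3R2me2s library was a block of 3126 bp at chromosome 2, 101481829 to 101484954, with 3352 reads of H3R2me2s, 3208 of the combined mark and 54 of H3K4me3. H3R2me2s read starts filled 46.7% of its positions, which argues against a few amplified fragments, and at 2920 they outnumbered the 2595 distinct starts that independent placement of its reads gives, so repeated reads may have been removed in part before deposit. With filled positions allowed for, the CV of read density over 100 bp bins was 0.104 (0.036 to 0.146) for H3R2me2s and 0.058 (0 to 0.097) for the combined mark, and 0 of 200 strong regions of 3 to 5 kb (medians 0.913 and 0.929) and 0 of 200 of 6 kb or more (0.722 and 0.723) were as low as the upper bound of either, which argues against marked chromatin. Read density was 1072 times that of the 500 bp on each side for H3R2me2s (exact interval 192 to 42366, with 1 read in the sides), 147 times for the combined mark (71.1 to 365, with 7 reads) and 1.23 times for H3K4me3 (0.676 to 2.41), so extra copies of a DNA stretch in the first 2 preparations are a candidate explanation. The 1800 bp stretch and the chromosome 4 window above also set the first 2 libraries apart from the H3K4me3 library. The preparations may then differ in more than the antibody, which bears on every comparison with H3K4me3.

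The combined mark rose faster than H3K4me3 across the H3K4me3 classes. Ranked and measured on separate reads, its net ratio to H3K4me3 was 1.78 times as high in the strongest class as in the weakest, which argues against noise in the ranking. It was 1.23 times as high in the strongest class as in the next one, where background is a small part of the level. That argues against background in weak bins as the cause of the rise between those classes. How far background shapes the weaker classes is not addressed by that comparison. Relative to H3R2me2s, which involves no H3K4me3 value, it was 1.31 times as high in the strongest class as in the middle one. H3R2me2s was only 6.26 times background in the middle class, where a raised local background would lower that ratio. In the fourth class the ratio was 2.95 and in the strongest 3.20. The comparison therefore does not decide whether H3K4me3 levelled off, which stays open. An antibody that binds H3K4me3 more readily in dense chromatin, and a true rise in doubly marked tails, also stay open and were not tested.

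H3R2me2s was called without H3K4me3 in 1984 bins, 6 of them in the chromosome 2 segment and 51.2% within 5 kb of an H3K4me3 bin. When bins outside that segment were called on part of the reads, 349 bins stood at 10.1 times background in the reads used and at 4.48 times (4.13 to 4.85) in the rest, which argues against chance over average background as the whole cause, while a chance excess over a raised local level stays open; with the segment included the first run of this test gave a higher level, and the segment was then left out. Median H3K4me3 was 4.03 times background in the 1984 bins, and the H3R2me2s level in the remaining reads was 1.04 times the larger of the other levels. H3K4me3 below the calling limit and a raised background common to the 3 libraries cannot be told apart, because no input library was used here. No biological explanation was tested.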
